A study of Mus musculus with 16 samples.

How the data were processed

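The series holds single-cell RNA sequencing of mouse CD8+ T cells that bound the AH1 tetramer and were sorted live. AH1 is a peptide of the envelope protein of an endogenous murine leukaemia virus, presented by H-2Ld in BALB/c mice, so the tetramer marks T cells specific for an antigen of several BALB/c tumours. The tumour model and the antibody schedules are not given in the sources used here. Of the 16 libraries, 12 came from the tumour microenvironment and 4 from tumour-draining lymph nodes, in 8 groups of 2. The tumour groups were wild type, Cd69 knockout, control IgG, anti-CD69, anti-PD-1, and anti-CD69 with anti-PD-1 (the combination), and the node groups were wild type and Cd69 knockout. Replicates are not stated to be separate animals, nor their numbers to pair samples, so edgeR p-values measure spread between these libraries. Camera and Fisher tests compare genes.

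The deposited matrices hold raw UMI counts per gene and cell barcode, already reduced by the authors to barcodes called as cells. The libraries were made with 10x Genomics Chromium 3' reagents. The submitters' processing notes name Cell Ranger 6.0.0 and mm10. The file headers give Cell Ranger 3.0.2 for the tumour libraries, with 31053 genes listed, and 6.0.0 for the node libraries, with 32285 genes, so tissue goes together with the software version and the gene annotation. The 30406 gene identifiers present in both lists were used, of which 30329 (99.75%) matched GENCODE coordinates on GRCm38.

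Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 112608 of 129230. A cluster of 277 B cells in the nodes was then removed, and 112331 cells were analysed, 4028 to 12129 per library with a median of 4981 to 9503 UMIs. In wild-type tumour replicate 2, 30.2% of the barcodes exceeded 10% mitochondrial UMIs. Scrublet with its own threshold called at most 0.0497% of the cells of a library as doublets, far below the rate of the method, so its calls were not used and an alternative left out the highest scores instead. The counts of the kept cells were summed per library, giving 39403678 to 86580999 UMIs.

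Summed counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr, robust estimation, group means over all 16 libraries), which tested 14156 genes in each of 13 comparisons. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05, and the adjusted p-values of genes in the text are from this test. CPM values are UMI counts scaled to library size with the TMM factors, and errors are standard deviations (SD) of CPM or standard errors (SE) of log2 fold changes, with 2 libraries per group. Between replicates, the mean squared difference over that of counting error ranged from 9.33 in knockout nodes and 11.6 in wild-type nodes to 93.6 in wild-type and 138 in knockout tumours. A simulation at these depths gave all groups equal spread per gene, so its rates may not hold here. This fit recovered 50.0% of genes raised and 44% lowered 2-fold between node genotypes, and 56.0% and 42% in tumours. Of calls, 2.08% and 1.05% were false.

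The 28 gene lists, 483 genes of which 395 were tested, covered T cell states, signalling, metabolism, cell cycle, stress and other cell types. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. With the preset value 101 list calls passed over the 13 comparisons and with the estimated correlation 1 did, that of inhibitory receptors between tumour and node in the knockout. Members were counted as higher or lower by the edgeR test adjusted over all genes and also adjusted over the list alone. Of the listed symbols, 9 matched no single shared identifier.

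Cells of each tissue were clustered apart with scanpy 1.11.5 and igraph 0.11.9 (2000 variable genes, 30 principal components, 15 neighbours, resolution 0.8), leaving out Cd69, T cell receptor and immunoglobulin segments, and mitochondrial, ribosomal and sex-linked genes. Clusters were named by markers that were fixed, but the thresholds for a name (at least 3 markers of the class among the top 25 genes, a mean log2 fold of at least 0.4 and 200 cells) were set after the clusters were seen. Tumour cluster 0 met them for terminally exhausted cells although Fcer1g, a gene of another list, was among its top 10 genes, and it is called by its number. Cells per cluster were tested with edgeR. To measure change within a class, counts were also summed over the cells of the class where every library of a comparison held at least 50. Node cells were clustered again without the 120 genes called between genotypes. Cells with a UMI of Tcf7 or of Havcr2 were counted after each cell was thinned to 3000 UMIs, which leaves out cells with fewer, up to 18.6% of cells in wild-type tumours.

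Genes were named by a fixed rule: a panel of 21 T cell genes; the 5 highest and 5 lowest log2 fold changes among called, named genes with at least 20 CPM in the higher group and groups that did not overlap, without T cell receptor, immunoglobulin, mitochondrial, Xist and Y-linked genes; and up to 4 members per list with the smallest adjusted p. Values of 2 genes that this rule names, and their alternatives, are not reported here. In comparisons beyond the effects of the knockout, of each antibody and of the combination against IgG or anti-PD-1, the panel was limited to Cd69 and Pdcd1, and at least the first 3 genes each way were named. The samples, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were RLE factors, DESeq2 1.42.0, no filter on low counts, only the libraries of a comparison, the replicate number as a block, all barcodes passing the cell filter, a stricter cell filter (1000 genes, 5% mitochondrial UMIs), no cells with the highest doublet scores, thinned counts, other resolutions and thinning depths, an estimated correlation, and leaving out each library in turn. Groups of 2 are too small for a test over other splits of the samples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.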

Results

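RNA of single AH1 tetramer-positive CD8+ T cells was counted in 16 libraries, 2 in each of 8 groups. After filtering, wild-type tumours gave 17469 cells, Cd69 knockout tumours 14974, IgG 13275, anti-CD69 12645, anti-PD-1 12110 and the combination of both antibodies 11400. The tumour-draining lymph nodes gave 13006 wild-type and 17452 knockout cells. Summed per library, replicates 1 and 2 held 68421149 and 52549109 UMIs in wild-type tumours and 56088693 and 86580999 in knockout tumours. With IgG they held 72644997 and 77086211 UMIs, with anti-CD69 63278333 and 67752856, with anti-PD-1 62646677 and 54923112, and with the combination 52870633 and 39403678. In nodes they held 61176147 and 58855587 UMIs in the wild type and 65161291 and 78074813 in the knockout. CD69 is a membrane protein induced within hours of T cell activation that holds cells in tissue by binding the egress receptor S1PR1, and PD-1 is an inhibitory receptor of activated and exhausted T cells.

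The first question was what loss of Cd69 changed in tumour CD8+ T cells. Cd69 itself (ENSMUSG00000030156, GRCm38 chromosome 6: 129267325 to 129275436) fell by a log2 fold change of -4.20 ± 0.16 (SE, n = 2 libraries per group; adjusted p = 9.9e-08), from 139 ± 19.7 to 7.55 ± 1.41 CPM (SD). Among the called genes of the naming rule, the highest rises were in Ly6c1 (2.39 ± 0.37, adjusted p = 0.0104), Ly6c2 (2.36 ± 0.36, adjusted p = 0.00933) and Ly6a (2.29 ± 0.38, adjusted p = 0.0115), surface proteins of memory and activated T cells that lie together on chromosome 15, from 74994877 to 75111970. Ly6c2 went from 61.4 ± 4.90 to 314 ± 138 CPM. The chemokine receptor Ccr2 (chromosome 9: 124101950 to 124113557) rose by 2.11 ± 0.34 (adjusted p = 0.0111) and the chemokine Ccl5 (chromosome 11: 83525778 to 83530518) by 1.48 ± 0.32 (adjusted p = 0.0357), to 2440 ± 911 CPM. Besides Cd69, the lowest log2 fold changes among these genes were those of Klra3, an NK receptor gene (-6.90 ± 0.33, adjusted p = 3.7e-07), Sfmbt2, a Polycomb group gene (-6.40 ± 0.30, adjusted p = 3.7e-07), Pianp (-4.04 ± 0.25, adjusted p = 4.7e-06) and Tmprss6, a membrane serine protease (-1.73 ± 0.27, adjusted p = 0.0111). Klra3 and Pianp lie on chromosome 6 with Cd69, at 130323289 to 130337574 and 124996694 to 125003096. Sfmbt2 lies on chromosome 2, at 10370510 to 10595253. By the naming rule, the groups of these 10 genes did not overlap.

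None of the other panel genes passed the test in knockout tumours. The naive and memory genes had log2 values of -0.37 for Tcf7, 0.27 for Slamf6, 0.46 for Il7r, 2.24 for S1pr1 (adjusted p = 0.154) and -0.71 for Klf2. The exhaustion genes had 0.11 for Pdcd1 (adjusted p = 0.834), -0.40 for Tox, 0.67 for Havcr2 (adjusted p = 0.280), 0.48 for Lag3 (adjusted p = 0.0848) and 0.44 for Entpd1. The effector genes had 0.88 for Gzmb (adjusted p = 0.140), 0.21 for Prf1, 0.03 for Ifng and 0.25 for Ccl4. Itgae had 0.00, Cxcr6 0.44, Cx3cr1 0.22, Nr4a1 -0.14 and Mki67 -0.50.

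The test called 310 of 14156 genes between knockout and wild-type tumours, 181 higher and 129 lower, of which 150 differed by at least 2-fold. DESeq2 called 801. Leaving out wild-type replicate 2 gave 26 genes, leaving out knockout replicate 1 gave 657 and leaving out knockout replicate 2 gave 39, and a fit to these 4 libraries alone gave 6, without the 5 named genes that rose or Tmprss6. With a library left out the adjusted p ranged from 0.00337 to 0.264 for the 5 named genes that rose, none of which passed without wild-type replicate 2 or without knockout replicate 2, and that of Ccl5 did not pass without wild-type replicate 1 either. Of the 5 that fell, Tmprss6 did not pass without wild-type replicate 2 (adjusted p = 0.0957), and the other 4 passed each time.

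Interferon response genes were higher as a list in knockout tumours (camera adjusted p = 7.7e-11; 0.401 with an estimated correlation). Of 23 measured, 4 rose and 0 fell, 15 rose when adjusted over the list alone, and 22 had a positive log2 value, with a median of 0.71. Those that rose included the antiviral genes Ifit1 (1.38 ± 0.30, adjusted p = 0.0376) and Ifit3 (1.28 ± 0.26, adjusted p = 0.0291), the nucleic acid sensor Zbp1 (0.61 ± 0.14) and Xaf1 (0.62 ± 0.14). Genes of oxidative phosphorylation were also higher (adjusted p = 5.9e-07; 0.401 with estimated correlation), with 5 of 21 risen, 0 fallen and 10 risen adjusted over the list alone, among them Ndufa1 (0.95 ± 0.18), Ndufa2 (0.64) and Cox6c (0.70), subunits of respiratory complexes I and IV. Cytotoxic genes were higher (adjusted p = 2.5e-05; 0.422 with estimated correlation): 0 of 17 passed and 4 rose adjusted over the list alone, and all 17 values were positive, such as 1.32 for the granzyme gene Gzmm (adjusted p = 0.0517), 0.82 for Gzmk (adjusted p = 0.0701) and 0.47 for the receptor Klrk1. Circulating effector genes (adjusted p = 0.0101; 0.422 with estimated correlation) had 1 of 17 risen and 5 adjusted over the list alone. Inhibitory receptors (adjusted p = 0.0219; 0.401 with estimated correlation) had 1 of 12 risen and 2 adjusted over the list alone, with Lilrb4a at 1.12 (adjusted p = 0.0231).

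S phase and G2/M genes were lower as lists in knockout tumours (adjusted p = 2.5e-05 and 0.000435; adjusted p = 0.516 and 0.666 with estimated correlation). Of 20 S phase genes 0 passed, 4 fell adjusted over the list alone, and 19 had negative values, such as -0.50 for Rrm1 and -0.62 for Mcm3, which act in DNA replication. Of 22 G2/M genes 0 passed, also adjusted over the list alone, and all 22 values were negative, with -0.58 for Bub1b and -0.40 for Cenpa. Macrophage and monocyte genes, markers of cells the sort should remove, were higher as a list (adjusted p = 0.00563; 0.401 with estimated correlation), with 1 of 9 risen, also adjusted over the list alone. That gene was Ly6c1, which T cells express, and Lyz2 had 2.06 ± 0.75 (adjusted p = 0.189) and C1qa 1.66. The 79 genes near Cd69 on chromosome 6 were higher as a list (adjusted p = 0.0491; 0.401 with estimated correlation), with 4 risen, 4 fallen, and 21 risen and 9 fallen adjusted over the list alone. Without knockout replicate 2 the S phase list gave an adjusted p of 0.164, the circulating effector list 0.301 and the G2/M list 0.364 with its direction turned. Without wild-type replicate 2 the inhibitory receptors gave 0.0688, the circulating effector, cytotoxic and macrophage lists 0.0919 each and the Cd69 neighbours 0.285. Without knockout replicate 1 the inhibitory receptors gave 0.122 and the neighbours 0.224.

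**Figure D1:**
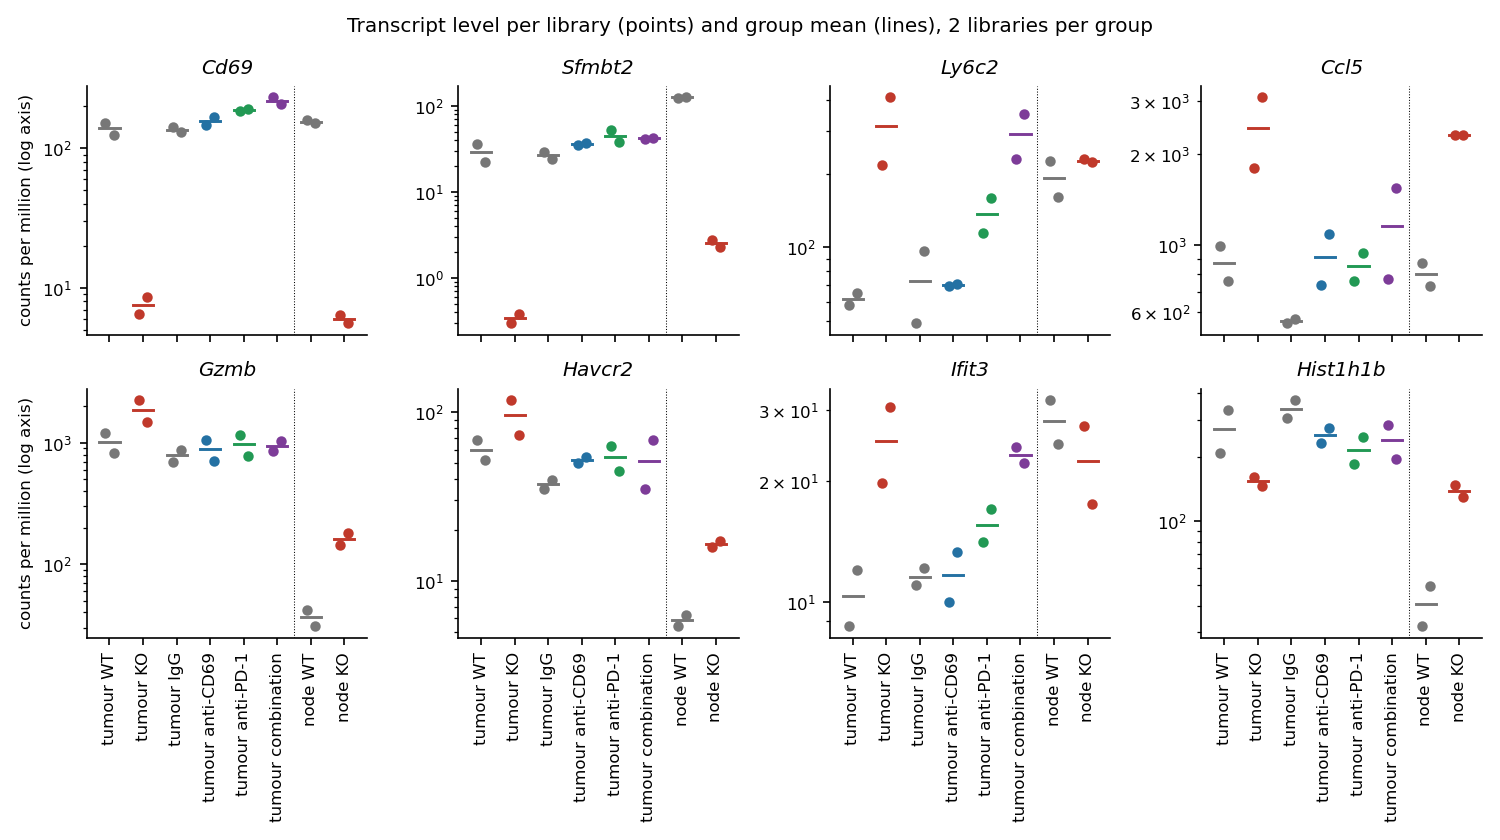
CPM (log axis) of 8 genes in each of the 16 libraries, by group, with 1 point per library. Cd69 was at 139 ± 19.7 CPM in wild-type and 7.55 ± 1.41 CPM in knockout tumours (SD, n = 2), and Gzmb at 36.4 ± 7.88 and 162 ± 26.0 CPM in wild-type and knockout nodes.

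The same question was asked in tumour-draining lymph nodes. In knockout node cells Gzmb (chromosome 14: 56258838 to 56262260), the cytotoxic protease granzyme B, rose by a log2 fold change of 2.15 ± 0.30 (SE, n = 2; adjusted p = 0.00589), from 36.4 ± 7.88 to 162 ± 26.0 CPM. The cell cycle gene Cdca3 rose by 1.87 ± 0.30 (adjusted p = 0.0138) and the linker histone gene Hist1h1b by 1.76 ± 0.27 (adjusted p = 0.01001), Ccr2 by 1.86 ± 0.33 (adjusted p = 0.0233) and Ccl5 by 1.53 ± 0.32 (adjusted p = 0.0488). A pair of exhaustion markers of the panel also rose, Havcr2, which encodes TIM-3, by 1.503 ± 0.31 (adjusted p = 0.0458) and Entpd1, which encodes CD39, by 1.06 ± 0.19 (adjusted p = 0.0233), both from low levels: Havcr2 went from 5.83 ± 0.626 to 16.5 ± 0.951 CPM. Cd69 fell by -4.69 ± 0.17 (adjusted p = 3.4e-08), Sfmbt2 by -5.64 ± 0.26 (adjusted p = 3.8e-07) and Pianp by -3.42 ± 0.24 (adjusted p = 2.4e-05). The Wnt ligand gene Wnt10a fell by -1.44 ± 0.28 (adjusted p = 0.0379) and Spry2, an inhibitor of receptor tyrosine kinase signalling, by -1.33 ± 0.25 (adjusted p = 0.0296). The groups did not overlap, by the naming rule or, for Havcr2 and Entpd1, without it.

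The other panel genes did not pass in nodes. Their log2 values were -0.42 for Tcf7, -0.24 for Pdcd1, -0.17 for Slamf6, -0.37 for Tox, -0.25 for Lag3, 0.46 for Prf1, -0.25 for Ifng and 0.18 for Ccl4. They were 0.28 for Il7r, 0.55 for S1pr1, 0.35 for Klf2, -0.91 for Itgae (adjusted p = 0.199), 0.46 for Cxcr6, 0.42 for Cx3cr1, -0.72 for Nr4a1 and 0.78 for Mki67 (adjusted p = 0.380). The test called 120 genes, 76 higher and 44 lower, and DESeq2 called 331. With 1 library left out it called 16 genes without wild-type replicate 1, 27 without wild-type replicate 2, 26 without knockout replicate 1 and 34 without knockout replicate 2, and a fit to the 4 node libraries alone called 2334, of which 112 were among the 120. Cd69, Sfmbt2 and Pianp passed each time a library was left out; for the others the adjusted p reached 0.105 for Gzmb, 0.171 for Hist1h1b, 0.272 for Cdca3, 0.250 for Ccr2, 0.416 for Ccl5, 0.524 for Havcr2, 0.247 for Entpd1, 0.392 for Wnt10a and 0.319 for Spry2. Gzmb, Hist1h1b and Spry2 did not pass in the fit to the node libraries alone, and Havcr2, Entpd1, Cdca3, Ccr2, Hist1h1b and Wnt10a did not pass without cycling cells. Ccl5 and Havcr2 did not pass with no filter on low counts, with the stricter cell filter, without the highest doublet scores or without genes within 20 Mb of Cd69. Ccl5 also did not pass with RLE factors or with all barcodes that passed the cell filter, Ccr2 with no filter on low counts and Wnt10a without the highest doublet scores.

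Cell cycle genes were the lists with the smallest p in knockout nodes. Of 22 G2/M genes 3 rose, 20 rose adjusted over the list alone and all 22 values were positive, with a median of 1.03 (adjusted p = 1.9e-22; 0.144 with estimated correlation). Among them were the cyclin gene Ccna2 (1.52 ± 0.31, adjusted p = 0.0488), Hmmr (1.12) and Kif23 (0.93). Of 20 S phase genes 2 rose, 15 rose adjusted over the list alone and all 20 were positive, with a median of 0.59 (adjusted p = 2.0e-19; 0.144 with estimated correlation). Among them were the origin licensing gene Cdc6 (1.399 ± 0.20, adjusted p = 0.00684) and the DNA methylation cofactor Uhrf1 (0.96 ± 0.16). Progenitor exhausted genes were lower (adjusted p = 2.0e-06; 0.209 with estimated correlation): 1 of 19 fell, the tetraspanin gene Cd81 (-0.79, adjusted p = 0.0361), 4 fell adjusted over the list alone, and Xcl1 had -1.02 (adjusted p = 0.0554) and Kit -1.35. Early genes of T cell receptor signalling were lower (adjusted p = 1.1e-06; 0.124 with estimated correlation), with 0 of 22 fallen, 1 adjusted over the list alone and 19 negative values, such as -0.81 for Dusp2 and -0.70 for Egr3. Circulating effector genes were higher (adjusted p = 0.000499; 0.209 with estimated correlation), with 0 of 17 risen and 5 adjusted over the list alone, with values of 2.29 for Gzma (adjusted p = 0.121) and 2.32 for Klrg1 (adjusted p = 0.235). Cytotoxic genes were higher (adjusted p = 0.00115; 0.365 with estimated correlation), with 1 of 17 risen, Gzmb, and 3 adjusted over the list alone.

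Among the other lists in nodes, oxidative phosphorylation was higher with 0 of 21 genes passed and all 21 values positive (median 0.15, adjusted p = 0.00188; 0.365 with estimated correlation). The Cd69 neighbours were higher with 9 of 79 risen and 4 fallen (adjusted p = 0.0394; 0.249 with estimated correlation), and 15 and 4 adjusted over the list alone. That list gave an adjusted p of 0.0671 without wild-type replicate 1 and 0.0991 without wild-type replicate 2. Markers of other cells were lower: in the CD4 and regulatory T cell list 1 of 10 fell, Izumo1r (-1.11, adjusted p = 0.0336), and 2 adjusted over the list alone (adjusted p = 0.00733; 0.201 with estimated correlation). Of 2 erythroid genes 1 fell, Car2 (-0.97), also adjusted over the list alone (adjusted p = 0.00218; 0.124 with estimated correlation). Terminal exhaustion genes did not pass as a list, with a median of -0.02 and a mean of 0.20, and 3 of 22 rose.

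Class shares differed between node genotypes. When the cells were clustered without the 120 called genes, progenitor exhausted-like cells made up 12.8% ± 0.450 (SD, n = 2) of wild-type and 6.47% ± 0.0552 of knockout cells (log2 ratio -0.98, edgeR adjusted p = 0.00111), and naive-like cells 10.6% ± 0.382 and 5.88% ± 0.473 (adjusted p = 0.0023). Cycling cells made up 2.82% ± 0.238 and 6.50% ± 0.337 (log2 ratio 1.21, adjusted p = 0.00111), terminally exhausted-like cells 10.5% ± 0.960 and 17.4% ± 0.462 (adjusted p = 0.00353) and circulating effector-like cells 5.41% ± 1.34 and 9.40% ± 0.779 (adjusted p = 0.0204). Interferon-responsive cells were 5.93% ± 1.41 and 4.47% ± 1.87 (adjusted p = 0.341). In the first clustering, which used the called genes, terminally exhausted-like cells were 2.66% ± 0.415 and 8.32% ± 0.462 (log2 ratio 1.64, against 0.73 without these genes) and circulating effector-like cells 3.51% ± 1.14 and 11.05% ± 1.79 (1.65 against 0.80), but these names covered partly other cells. The terminally exhausted-like class was first clusters 7 and 14 (1779 cells). Without these genes it was a cluster of 4396 cells led by AA467197, Plac8, Spp1 and Csf1, sharing 1442. The circulating effector-like classes of 2455 and 2380 cells shared 1592, and 590 of the 2380 were first naive-like. The naive-like classes of 4498 and 2389 shared 2308. The cells named progenitor exhausted-like were led by Cxcl10, Hivep3, Egr3 and Egr2, with Xcl1, Cd83, Id3 and Tnfsf8 as markers and without Tcf7 or Slamf6 among their top 25 genes. At a resolution of 1.2 no node cluster had this name. In the first clustering 7 of 15 node clusters passed, and 0 passed without wild-type replicate 1. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.33.

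**Figure D2:**
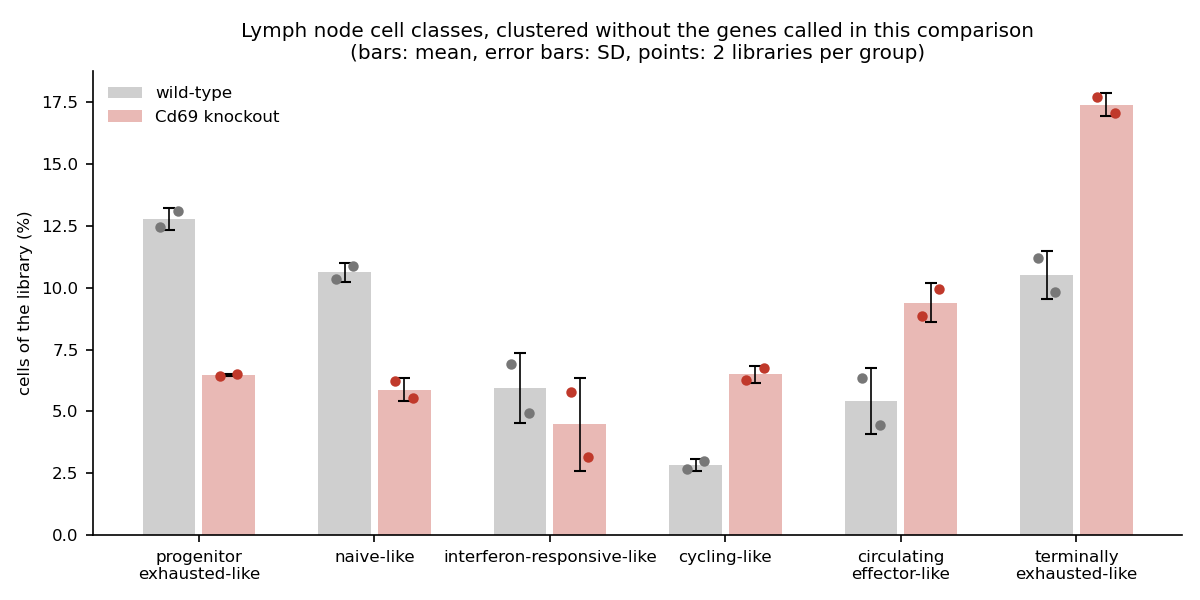
Share of cells (%) in each class of lymph node cells, clustered without the genes called between genotypes, with bars at the mean, error bars of 1 SD and a point per library (n = 2). Cycling-like cells were 2.82% in the wild type and 6.50% in the knockout.

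In tumours 0 of 112 edgeR tests of 14 clusters in 8 comparisons passed, with 5 at an unadjusted p under 0.05, no other tool was run, and 6 passed without knockout replicate 1. Cluster 8, led by Mt1, Ccl5 and Ly6c2, held 0.540% of cells in knockout replicate 1 and 42.9% in knockout replicate 2, so the knockout tumour libraries differed from each other. Cluster 9, with a median of 1140 UMIs and 665 genes per cell, held 15.7% of wild-type replicate 1, 1.99% of replicate 2 and 0.0235% to 2.30% of the other libraries, so the wild-type tumour libraries, which are also in the control comparison with IgG, differed too. With the stricter cell filter 304 genes differed between genotypes in tumours, and without wild-type replicate 1 it was 294, of which 289 and 186 were among the 310. Interferon-responsive cells made up 5.80% ± 0.0127 with IgG and 9.87% ± 0.0877 with the combination. After thinning to 3000 UMIs, cells with Tcf7 and no Havcr2 were 56.8% ± 0.531 of wild-type and 42.9% ± 0.781 of knockout nodes. Tcf7 also marked naive-like cells, so this is no progenitor share. Cells with Havcr2 and no Tcf7 were 1.14% ± 0.0178 and 3.30% ± 0.136. Among 244 B cells of the nodes, which should lack both, 8.20% were Tcf7-only and 0 were Havcr2-only, which allows up to 1.23%, at a median of 5196 UMIs against 7336 in node T cells. The Havcr2-only share of wild-type nodes lies below that limit. In tumours the Havcr2-only share was 13.2% ± 1.21 in the wild type, 18.1% ± 5.43 in the knockout, 8.09% ± 1.02 with IgG, 11.8% ± 0.730 with anti-CD69, 11% ± 3.20 with anti-PD-1 and 10.7% ± 4.23 with the combination. The Tcf7-only share in tumours was 8.68% ± 1.54 in the wild type, 6.29% ± 3.86 in the knockout, 10.9% ± 0.779 with IgG, 8.74% ± 1.91 with anti-CD69, 13.2% ± 7.55 with anti-PD-1 and 12.1% ± 0.102 with the combination, and no background was measured in tumours.

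Changes within classes of cells were also tested, where a class can pool clusters whose mix differs between libraries. In progenitor-like tumour cells 117 genes differed between genotypes, 58 higher and 59 lower, with Cd69 at -4.69, C2cd4b at -2.74, Gzmm at 1.73 and the protease inhibitor gene Ctla2a at 1.23. That count was 30 without wild-type replicate 2, 200 without knockout replicate 1 and 35 without knockout replicate 2. The class pools tumour clusters 2 and 3, and cluster 2, which has C2cd4b among its top 10 genes, held 58.8% of it in the wild type and 64.0% in the knockout, 26.4% in replicate 1 and 82.4% in replicate 2. In clusters 2 and 3 alone C2cd4b had -2.95 and -2.255, Gzmm 1.67 and 1.72 and Ctla2a 1.09 and 1.37, and each passed. With a library left out these calls held, except in cluster 2 for Gzmm and Ctla2a without knockout replicate 2 (adjusted p = 0.308 and 0.283) and for Ctla2a without wild-type replicate 2 (adjusted p = 0.110). Progenitor-like node cells were those of node cluster 4, led by Cxcl10, Wnt10a, Hivep3 and Egr2. In them 15 genes differed, 4 higher and 11 lower, among them Gzmb at 2.42 (16.4 against 3.05 CPM) and the NK receptor gene Klrd1 at 1.33. It was 8 without wild-type replicate 1, without knockout replicate 1 or without knockout replicate 2. In tumour cluster 0, 35 genes differed, with Cnih2 at 1.63 and Mmd at -1.06. Without wild-type replicate 1 it was 56, without wild-type replicate 2 it was 11, without knockout replicate 1 it was 13 and without knockout replicate 2 it was 15. In terminally exhausted-like node cells 30 differed, 27 of them lower, among them Izumo1r (-3.21), the integrin gene Itgae (-2.40, 9.49 against 49.9 CPM) and Lag3 (-0.98, 189 against 373 CPM). There it was 16 without wild-type replicate 1, 10 without wild-type replicate 2, 14 without knockout replicate 1 and 18 without knockout replicate 2. This class pools node clusters 7 and 14, and cluster 14, which has Izumo1r, Itgae and Lag3 among its top 25 genes, held 38.2% of its wild-type and 9.96% of its knockout cells. In cluster 7 alone Izumo1r had -0.30, Itgae -1.05 and Lag3 0.12, and none passed, so the pooled values follow the mix in part. In cluster 14 alone Izumo1r had -1.84 (adjusted p = 0.000463, and up to 0.0452 with a library left out), Itgae -1.49 (adjusted p = 0.245) and Lag3 -0.94 (adjusted p = 0.0431, and 0.111 to 0.455 with a library left out). For the antibodies edgeR called 0 genes in progenitor-like cells with anti-CD69 against IgG, the combination against IgG and the combination against anti-PD-1, with 564, 1077 and 312 at an unadjusted p under 0.05. It called 1 with anti-PD-1 against IgG, C2cd4b (-1.21), and 0 with any 1 library of that comparison left out. Cluster 2 held 70.6% of the class with IgG and 39.6% with anti-PD-1. C2cd4b had -0.85 in cluster 2 alone (adjusted p = 0.729) and -1.23 in cluster 3 alone (adjusted p = 0.0258), which did not pass without IgG replicate 1 or either anti-PD-1 library (adjusted p = 0.100 to 1). In tumour cluster 0 it called 0 genes for anti-CD69, anti-PD-1 and the combination against IgG and for the combination against anti-PD-1, with 512, 527, 813 and 409 at an unadjusted p under 0.05. Without combination replicate 1 the combination against IgG gave 51 genes in progenitor-like cells and 52 in cluster 0, and the combination against anti-PD-1 gave 10 in cluster 0. With any other antibody or IgG library left out at most 2 genes passed, and no other tool was run within classes.

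The difference of the knockout effects asked whether loss of Cd69 acted differently in tumour and node. Hist1h1b (-2.58 ± 0.38, adjusted p = 0.0236), the peroxiredoxin gene Prdx4 (-2.08 ± 0.28, adjusted p = 0.0169) and Uhrf1 (-1.48 ± 0.23, adjusted p = 0.0322) had lower knockout effects in tumours than in nodes. Cnih2, which encodes a partner of glutamate receptors, had a higher one (1.87 ± 0.23, adjusted p = 0.0137). In all 14 genes differed, 3 higher and 11 lower, and DESeq2 gave 248. As lists, S phase (median -0.91, adjusted p = 1.6e-21) and G2/M genes (median -1.25, adjusted p = 4.7e-22; 0.198 with estimated correlation for both) had lower effects in tumours. Of 20 S phase genes 1 passed, and 19 adjusted over the list alone; of 22 G2/M genes 0 passed, and 19 adjusted over the list alone. Interferon response genes had higher effects in tumours (0 of 23 passed and 9 adjusted over the list alone, median 0.75, adjusted p = 2.2e-13; 0.357 with estimated correlation). So did macrophage genes (0 of 9 and 1 adjusted over the list alone, adjusted p = 0.00137; 0.198 with estimated correlation) and oxidative phosphorylation (0 of 21, also adjusted over the list alone, adjusted p = 0.0159; 0.713 with estimated correlation). The panel genes had differences of 0.50 for Cd69, 0.34 for Pdcd1 and -1.27 for Gzmb, and none passed. With a library left out the count ranged from 1 without tumour knockout replicate 2 to 356 without tumour knockout replicate 1, and without cycling cells it was 4. None of the 4 named genes passed in every such fit, with an adjusted p of up to 0.3302. The oxidative phosphorylation list gave 0.312 without tumour wild-type replicate 2 and 0.250 without tumour knockout replicate 1.

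Genes near Cd69 on chromosome 6 were called more often than others, and in tumours this was not shown outside the Klr and Clec gene families. Of 288 tested genes within 20 Mb of Cd69, 15 passed in nodes (5.21%) and 16 in tumours (5.56%), against 104 (0.750%) and 293 (2.11%) of 13867 others (two-sided Fisher's exact test, p = 1.8e-08 and 0.000605). Without genes named Klr or Clec it was 2.29% against 0.750% in nodes and 2.67% against 2.11% in tumours (Fisher's exact test over 262 near genes, p = 0.0166 and 0.512). Calls left in nodes were Gm26826, Pianp, Emp1 and, with log2 0.02, -0.13 and 0.32 in tumours, Ncapd2, Foxm1 and Cdca3. Without Cd69, the 22 called in either tissue lay between 118501308 and 136810074, and 21 had the same sign in both. The NK receptor genes Klra3, Klri1, Klri2 and Klrb1f fell in both tissues, while Klra1, Klra4 and Klra8 had about 0 CPM in the wild type and rose in the knockout. Across genes, the knockout effects in tumour and node correlated with r = 0.325 (Spearman 0.167), with r = 0.342 (Spearman 0.0559, 52.7% of the same sign) over genes with a mean of at least 20 CPM, and with r = 0.270 without genes within 20 Mb, where genes are not independent replicates. Of the genes that fell in knockout tumours, 96 of 129 had a negative value in nodes (camera p = 1.5e-25; 0.00247 with estimated correlation), and of those that rose 152 of 181 had a positive value (p = 3.8e-16; 0.0463 with estimated correlation, and 0.0704 without genes within 20 Mb). Of the genes that fell in knockout nodes, 41 of 44 had a negative value in tumours (p = 3.6e-32; 2.2e-05 with estimated correlation). Of those that rose in nodes, 40 of 76 had a positive value in tumours (p = 0.0199; 0.440 with estimated correlation), and 32 of 67 without genes within 20 Mb (median -0.07). In all 13 genes rose and 21 fell in both tissues.

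**Figure D3:**
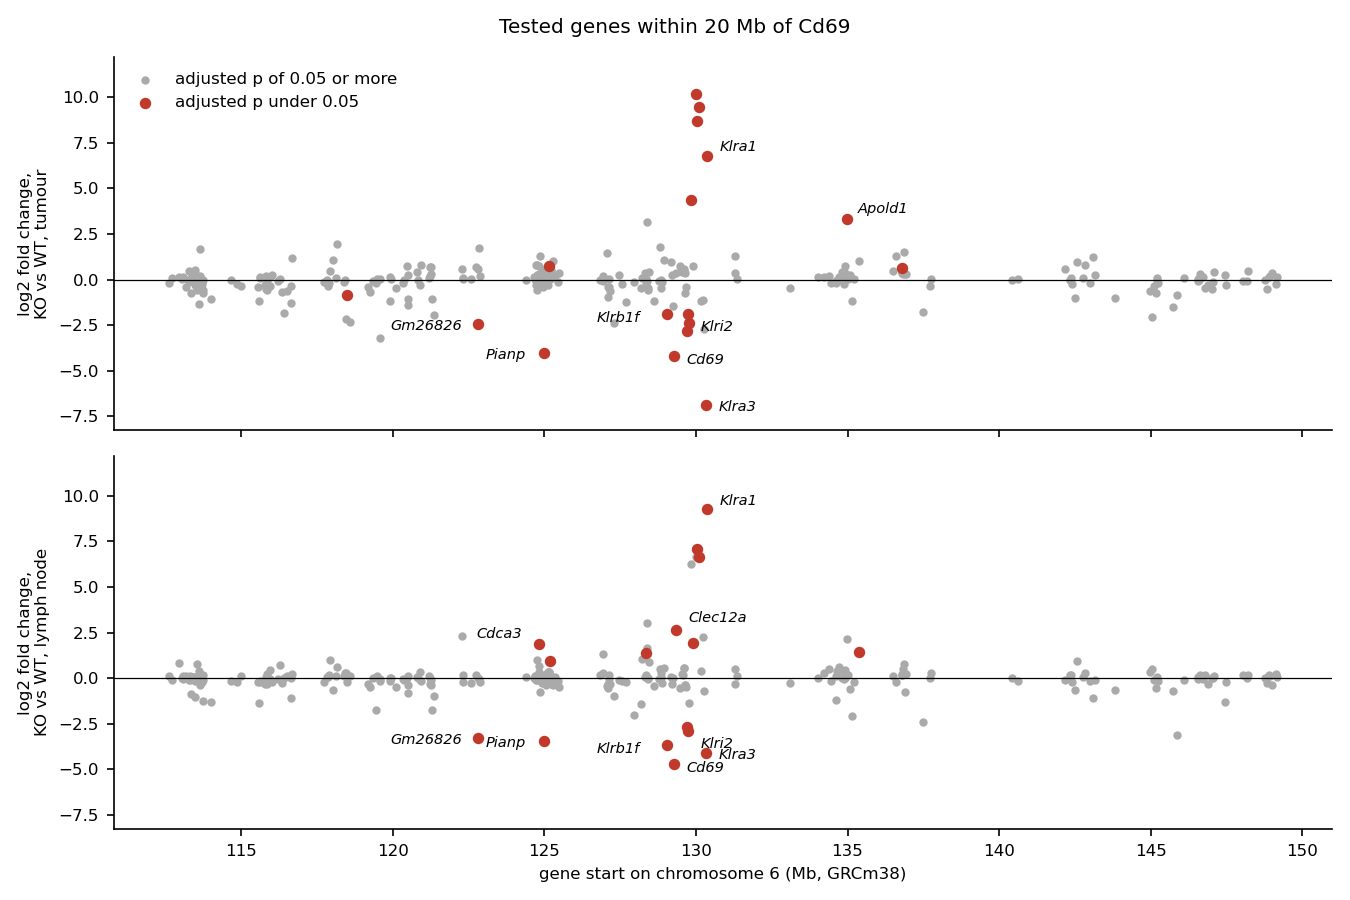
Log2 fold change of knockout against wild type (vertical axis) of genes within 20 Mb of Cd69 by position on chromosome 6 (Mb, GRCm38), in tumours and nodes. Cd69 has -4.20 and -4.69, and the fitted values of Klra genes with about 0 counts in the wild type depend on the prior count.

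The antibody comparisons asked what blocking CD69, PD-1 or both changed in tumour cells. Anti-CD69 against IgG left Cd69 mRNA at 157 against 136 CPM (log2 0.21 ± 0.14, SE, n = 2). The cytokine genes Il2, Ccl3 and Ccl4 had 1.97, 1.12 and 0.90, and none of these passed (adjusted p = 0.943). Of the panel, Pdcd1 had -0.17, Tcf7 -0.32, Slamf6 -0.05, Il7r -0.11, S1pr1 0.54, Klf2 0.39 and Tox -0.09. Havcr2 had 0.48, Lag3 0.04, Entpd1 0.15, Gzmb 0.17, Prf1 0.37, Ifng 0.56, Itgae 0.08, Cxcr6 0.28, Cx3cr1 -0.25, Nr4a1 -0.34 and Mki67 -0.24. edgeR called 0 genes, with 584 at an unadjusted p under 0.05, and DESeq2 called 8. Without anti-CD69 replicate 2 edgeR called 2.

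As lists under anti-CD69, cytokines and chemokines were higher (0 of 15 passed, also adjusted over the list alone, 12 positive, median 0.56, adjusted p = 0.00514; 0.652 with estimated correlation). Early T cell receptor genes were lower (0 of 22, also adjusted over the list alone, 18 negative, median -0.36, adjusted p = 7.8e-05; 0.241 with estimated correlation), with -0.69 for Junb, -0.59 for Nfkbid and -1.18 for Cd83. Progenitor exhausted genes were lower (0 of 19, also adjusted over the list alone, median -0.32, adjusted p = 0.0189; 0.771 with estimated correlation). Oxidative phosphorylation was higher (0 of 21, also adjusted over the list alone, adjusted p = 0.00507; 0.771 with estimated correlation). The CD4 and regulatory T cell list was lower (0 of 10 and 1 adjusted over the list alone, adjusted p = 0.00507; 0.349 with estimated correlation). Hypoxia genes were lower by the test (0 of 15 and 1 adjusted over the list alone, adjusted p = 0.0446; 0.836 with estimated correlation), with a median of -0.11 and a mean of 0.01, the opposite sign. Without IgG replicate 1 the progenitor list gave 0.559, oxidative phosphorylation and hypoxia 0.167 each and the CD4 list 0.0889. Without IgG replicate 2 the cytokines gave 0.0590. Without anti-CD69 replicate 1 the progenitor list gave 0.261 and oxidative phosphorylation 0.834. Without anti-CD69 replicate 2 the cytokines gave 0.171, the CD4 list 0.189 and hypoxia 0.269 with its direction turned.

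Anti-PD-1 against IgG also gave 0 genes by edgeR, with 1098 at an unadjusted p under 0.05, and 6 by DESeq2. Cd69 had 0.47 (188 CPM, adjusted p = 0.599), the granzyme gene Gzmk 1.06, the progenitor regulator Id3 1.03, the immediate early gene Nr4a2 -0.88 and Cxcl10 -1.29. The panel gave -0.12 for Pdcd1, 0.37 for Tcf7, 0.41 for Slamf6, 0.30 for Il7r, 1.12 for S1pr1, 0.03 for Klf2 and -0.20 for Tox. It gave 0.53 for Havcr2, 0.21 for Lag3, 0.03 for Entpd1, 0.30 for Gzmb, 0.22 for Prf1, 0.11 for Ifng, 0.46 for Ccl4, -0.15 for Itgae, 0.13 for Cxcr6, 0.01 for Cx3cr1, -0.64 for Nr4a1 and -0.36 for Mki67. S phase genes were lower (0 of 20 passed, 18 negative, median -0.29, adjusted p = 5.6e-05; 0.905 with estimated correlation), with -0.38 for Pcna and -0.50 for Mcm3. Early T cell receptor genes were also lower (0 of 22, median -0.41, adjusted p = 0.00103; 0.300 with estimated correlation), with -0.85 for Nfkbid and -0.77 for Junb. Macrophage genes were higher (0 of 9, all 9 positive, adjusted p = 0.000802; 0.300 with estimated correlation), with 2.45 for Lyz2. Cytotoxic genes (0 of 17, and 1 adjusted over the list alone, adjusted p = 0.0397; 0.905 with estimated correlation) and Cd69 neighbours (0 of 79, adjusted p = 0.0397; 0.501 with estimated correlation) were higher, and the CD4 list lower (0 of 10, adjusted p = 0.0397; 0.501 with estimated correlation). Adjusted over the list alone, 0 members passed in the lists for which no such count is given. Without anti-PD-1 replicate 1 the early T cell receptor list gave 0.0878, the CD4 list and the neighbours 0.468 each and the cytotoxic list 0.867. Without anti-PD-1 replicate 2 the S phase list gave 0.287. Without IgG replicate 1 the cytotoxic list gave 0.103 and the CD4 list 0.150, and without IgG replicate 2 the neighbours gave 0.161.

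The combination against IgG gave 0 genes by edgeR, with 1741 at an unadjusted p under 0.05, and 177 by DESeq2, and edgeR called 49 without combination replicate 1. Interferon response genes were higher (0 of 23 passed, 12 adjusted over the list alone, 22 positive, median 0.72, adjusted p = 3.7e-11; 0.776 with estimated correlation), with 1.00 ± 0.26 for Ifit3 (adjusted p = 0.233), 0.82 for Usp18 and 0.50 for Xaf1. S phase genes were lower (0 of 20, 18 negative, median -0.36, adjusted p = 6.6e-07; 0.776 with estimated correlation), with -0.52 for Mcm3 and -0.39 for Rrm1. G2/M genes were also lower (0 of 22, 20 negative, median -0.26, adjusted p = 0.00482; 0.858 with estimated correlation), with -0.52 for Bub1b. Cytokines (0 of 15, 13 positive, adjusted p = 0.000717; 0.776 with estimated correlation) and circulating effector genes (0 of 17, 1 adjusted over the list alone, adjusted p = 0.0219; 0.776 with estimated correlation) were higher, with 2.00 ± 0.35 for Ly6c2 (adjusted p = 0.196) and 1.28 for Gzmm. Cd69 had 0.69 ± 0.14 (219 ± 18.2 CPM, adjusted p = 0.205). The rest of the panel had -0.37 for Pdcd1, 0.24 for Tcf7, 0.49 for Slamf6, 0.02 for Il7r, 1.196 for S1pr1, 0.01 for Klf2 and -0.13 for Tox. Exhaustion and effector genes had 0.46 for Havcr2, 0.26 for Lag3, 0.05 for Entpd1, 0.26 for Gzmb, -0.15 for Prf1, 0.37 for Ifng, 0.75 for Ccl4, 0.46 for Itgae, -0.03 for Cxcr6, 0.14 for Cx3cr1, -0.02 for Nr4a1 and -0.28 for Mki67. In the lists for which no count adjusted over the list alone is given it was 0. The G2/M list gave an adjusted p of 0.303 without IgG replicate 2 and 0.539 without combination replicate 2, where the circulating effector list gave 0.297.

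Adding anti-CD69 to anti-PD-1, the comparison of the combination with anti-PD-1, gave 0 genes by edgeR, with 368 at an unadjusted p under 0.05, and 2 by DESeq2. All 23 interferon response genes were positive (0 passed, median 0.49, adjusted p = 2.5e-12; 0.550 with estimated correlation), with 0.56 for Slfn8, 0.31 for Zbp1 and 0.58 for Ifit3 (adjusted p = 0.961). Cytokines were higher (0 of 15, 14 positive, median 0.35, adjusted p = 4.2e-05; 0.524 with estimated correlation), with 0.58 for Csf2 and 0.46 for Xcl1. Early T cell receptor genes were also higher (0 of 22, 19 positive, adjusted p = 0.00386; 0.524 with estimated correlation), with 0.47 for Nfkbid, and so were circulating effector genes (0 of 17, 14 positive, adjusted p = 0.0450; 0.550 with estimated correlation). Glycolysis genes were lower (0 of 14, 12 negative, adjusted p = 0.00286; 0.550 with estimated correlation), with -0.73 for Eno1 and -0.56 for Pgk1. So were hypoxia (0 of 15, 13 negative, adjusted p = 0.00925; 0.550 with estimated correlation) and G2/M genes (0 of 22, 21 negative, adjusted p = 0.000164; 0.550 with estimated correlation). The panel had 0.22 for Cd69, -0.25 for Pdcd1, -0.13 for Tcf7, 0.08 for Slamf6, -0.28 for Il7r, 0.08 for S1pr1, -0.03 for Klf2 and 0.07 for Tox. There were values of -0.06 for Havcr2, 0.05 for Lag3, 0.02 for Entpd1, -0.04 for Gzmb, -0.37 for Prf1, 0.26 for Ifng, 0.29 for Ccl4, 0.60 for Itgae, -0.16 for Cxcr6, 0.12 for Cx3cr1, 0.62 for Nr4a1 and 0.08 for Mki67. Adjusted over the list alone 0 members of these 7 lists passed. Without anti-PD-1 replicate 1 the lists gave 0.174 for glycolysis, 0.248 for early T cell receptor genes and 0.391 for circulating effector genes. Without anti-PD-1 replicate 2 hypoxia gave 0.0744. Without combination replicate 1 hypoxia gave 0.117 and the early T cell receptor genes 0.146, and without combination replicate 2 the G2/M list gave 0.417 and the circulating effector list 0.431.

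**Figure D4:**
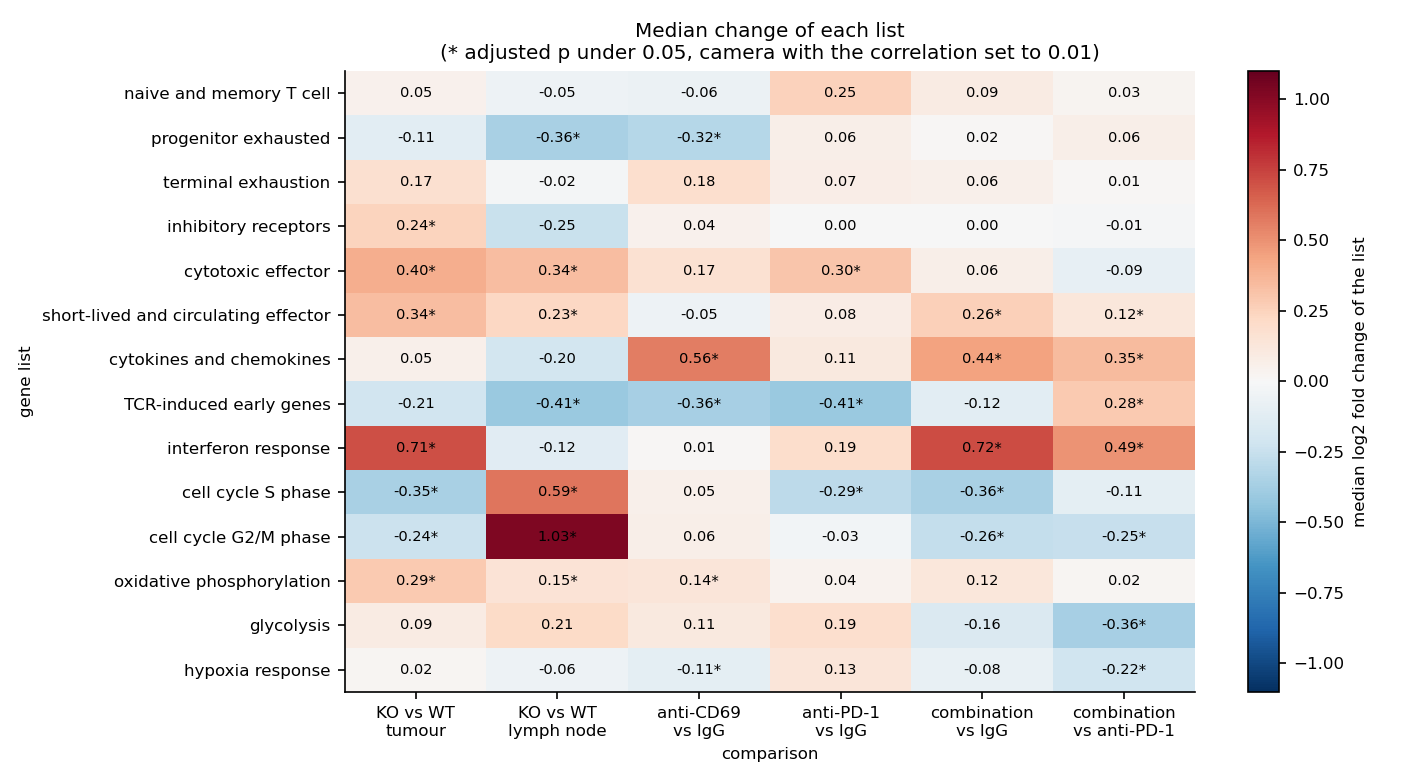
Median log2 fold change (colour) of 14 gene lists in 6 comparisons, with an asterisk where the adjusted p was under 0.05 with a correlation of 0.01. Interferon response genes had medians of 0.71 in knockout tumours, 0.72 in the combination against IgG and 0.49 in the combination against anti-PD-1.

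In the combination against anti-CD69 edgeR called 0 genes, with 1209 at an unadjusted p under 0.05, and DESeq2 57. edgeR called 17 without combination replicate 1 and 2 without anti-CD69 replicate 2. All 23 interferon response genes were positive (16 adjusted over the list alone, median 0.64, adjusted p = 6.9e-14; 0.735 with estimated correlation), and all 20 S phase genes were negative (adjusted p = 8.8e-10; 0.735 with estimated correlation). Of the S phase genes 0 passed adjusted over the list alone. Cd69 had 0.48 and Pdcd1 -0.20. For the interaction, which asks whether the combination differed from the sum of both antibodies, edgeR called 0 genes, with 550 at an unadjusted p under 0.05, and DESeq2 9. Early T cell receptor genes had positive values in 19 of 22 (median 0.69, adjusted p = 4.5e-06; 0.154 with estimated correlation), with 1.06 for Nfkbid and 0.94 for Junb, and interferon response genes in all 23 (median 0.45, adjusted p = 4.5e-06; 0.855 with estimated correlation). Adjusted over the list alone, 0 members of both lists passed. Cd69 had 0.01 and Pdcd1 -0.08.

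The knockout and the antibody were compared as 2 ways of removing CD69. In the difference of their effects Cd69 itself (-4.41 ± 0.21), Sfmbt2 (-6.83 ± 0.37), Klra3 (-6.77 ± 0.40), Pianp (-4.21 ± 0.33) and Tctex1d2 (-1.78 ± 0.28) were lower with the knockout, and Cnih2 (1.53 ± 0.23) and the receptor gene Slamf7 (1.00 ± 0.17) higher, each with an adjusted p under 0.05 in edgeR. In all 21 genes differed, 6 higher and 15 lower, and DESeq2 gave 126. It was 218 without knockout replicate 1, 12 without knockout replicate 2, wild-type replicate 2 or IgG replicate 1, 7 without IgG replicate 2 and 13 without anti-CD69 replicate 2. A fit without genes within 20 Mb of Cd69 gave 10. Cnih2, Slamf7 and Tctex1d2 did not pass in every such fit, with an adjusted p of up to 0.293. Pdcd1 had 0.27. All 23 interferon response genes had a higher effect in the knockout (8 adjusted over the list alone, adjusted p = 1.3e-09; 0.653 with estimated correlation). Across genes, the knockout and anti-CD69 effects in tumours correlated with r = -0.000939 (Spearman 0.0674), and with r = 0.163 over genes with a mean of at least 20 CPM, where genes are not independent replicates. The sign of r turned with the library left out, from -0.117 without knockout replicate 1 to 0.110 without wild-type replicate 1. Of the 181 genes that rose in knockout tumours, 136 had a positive value under anti-CD69 (camera p = 2.0e-07; 0.168 with estimated correlation). Of the 129 that fell, 67 had a negative value (median -0.02, p = 0.963; 0.984 with estimated correlation). The effects of anti-CD69 alone and on top of anti-PD-1 correlated with r = -0.107 (Spearman -0.209), and from -0.208 without combination replicate 2 to 0.0323 without anti-PD-1 replicate 1.

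Tumour and node cells were compared within each genotype, and there the software version and annotation differ with the tissue. In the wild type, tumour cells had higher granzyme F (Gzmf, 9.93 ± 1.78), Tmprss6 (8.45 ± 0.45), the Fc receptor chain gene Fcer1g (7.81 ± 0.33) and the heat shock genes Hspa1a (7.41 ± 0.81) and Hspb1 (6.93 ± 0.75), each with an adjusted p below 0.05. Igflr1 (-8.68 ± 0.32), Fdx2 (-8.42 ± 0.35), Rnasek (-7.83 ± 0.31) and Fam89b (-7.73 ± 0.23) were lower, and Tmsb15b2 had 0 UMIs in tumours and was at least 647-fold lower, against a floor of 3 counts over the group. Pdcd1 rose by 2.61, Havcr2 by 3.36, Entpd1 by 3.78 and Gzmb by 4.80, and Tcf7 fell by -3.08, S1pr1 by -4.25 and the integrin gene Itgae by -4.99, while Cd69 had -0.16 (adjusted p = 0.364). In all 7277 genes differed, 3644 higher and 3633 lower, and DESeq2 gave 7314.

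Terminal exhaustion genes rose in 19 of 22 (adjusted p = 4.5e-09; 0.0940 with estimated correlation), inhibitory receptors in 10 of 12 with 1 fallen (adjusted p = 0.000256; 0.0782 with estimated correlation). Glycolysis genes rose in 12 of 14 (adjusted p = 1.2e-05; 0.368 with estimated correlation), such as Slc16a3 (3.95) and Tpi1 (3.40). G2/M genes rose in all 22 and S phase genes in 19 of 20 (adjusted p = 3.0e-11 and 1.8e-09; 0.339 with estimated correlation for both). Tissue egress genes fell in 8 of 13 (adjusted p = 0.0120; 0.368 with estimated correlation), and progenitor exhausted genes fell in 11 of 19 (adjusted p = 0.00898; 0.427 with estimated correlation). The counts adjusted over the list alone were equal, except 9 fallen tissue egress genes. In the knockout, Gzmf (9.36 ± 1.54), Areg (8.10 ± 0.78), Gzmd (7.57 ± 1.79), Gzme (7.34 ± 1.49) and Fcer1g (6.63 ± 0.31) rose. Fdx2 (-8.25 ± 0.34), Igflr1 (-7.51 ± 0.29), Fam89b (-7.13 ± 0.22) and Cpne1 (-7.09 ± 0.33) fell, and Tmsb15b2 was at least 616-fold lower. Gzmd did not pass without node knockout replicate 1 or without node knockout replicate 2 (adjusted p up to 0.0559). Cd69 had 0.34 and Pdcd1 rose by 2.95. In the knockout 5769 genes differed, 2875 higher and 2894 lower, and DESeq2 gave 5958. It was 3470 without node knockout replicate 1 and 3498 without node knockout replicate 2. Inhibitory receptors rose in 11 of 12 (adjusted p = 2.0e-06; 0.0168 with estimated correlation), also adjusted over the list alone, the list call that passed with either correlation. Without genes that overlap another gene, 6621 genes differed in the wild type and 5220 in the knockout. Progenitor genes in the knockout gave an adjusted p of 0.0676 without tumour knockout replicate 1.

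Wild-type tumours without antibody and IgG tumours served as a control comparison. edgeR called 0 genes, with 259 at an unadjusted p under 0.05, and DESeq2 called 0. Cd69 had 0.03 and Pdcd1 -0.04. Terminal exhaustion (adjusted p = 0.00765; 0.529 with estimated correlation) and cytotoxic genes (adjusted p = 0.00523; 0.665 with estimated correlation) were higher in the wild type, and interferon response (median -0.16, adjusted p = 0.00765; 0.836 with estimated correlation) and oxidative phosphorylation genes (adjusted p = 3.1e-06; 0.529 with estimated correlation) lower, so list calls also arose between groups without a CD69 or PD-1 difference. In these lists 0 genes passed, also adjusted over the list alone. Without wild-type replicate 1 the terminal exhaustion list gave 0.658, the interferon list 0.923 and the cytotoxic list 0.658 with its direction turned, and without wild-type replicate 2 oxidative phosphorylation gave 0.553. Without IgG replicate 1 terminal exhaustion gave 0.179, and without IgG replicate 2 the interferon list gave 0.445.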

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

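The test without cycling cells was chosen after the result was seen, and the other tests of this part were planned. Each result below was singled out because the effect of the knockout differed between tumours and lymph nodes by a test of the difference itself.

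Between the tissues, 14 genes had knockout effects that differed in edgeR, with 1344 genes at an unadjusted p under 0.05 and 248 called by DESeq2. The effect on Cnih2 was higher in tumours by a log2 value of 1.865, with knockout tumours at 40.1 ± 1.26 CPM and wild-type tumours at 17.3 ± 3.08 CPM (SD, n = 2). Hist1h1b differed by -2.58, and went, from wild type to knockout, from 271 ± 89.1 to 154 ± 10.8 CPM in tumours and from 40.7 ± 12.4 to 138 ± 12.3 CPM in nodes. Prdx4, a peroxiredoxin of the endoplasmic reticulum, differed by -2.08 and the replication gene Uhrf1 by -1.48. Without cycling cells 4 genes differed, and Hist1h1b and Uhrf1 did not pass.

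Among the lists, S phase genes (adjusted p = 1.55e-21) and G2/M genes (adjusted p = 4.71e-22) had lower knockout effects in tumours than in nodes. Interferon response genes (adjusted p = 2.22e-13), oxidative phosphorylation (adjusted p = 0.0159) and macrophage and monocyte genes (adjusted p = 0.00137) had higher effects in tumours. None of these passed with an estimated correlation, where the adjusted p ranged from 0.198 for both cell cycle lists to 0.713 for oxidative phosphorylation.

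The count of 14 was 356 without tumour knockout replicate 1, 1 without tumour knockout replicate 2 or node wild-type replicate 1, 3 without tumour wild-type replicate 2, 6 without node wild-type replicate 2 and 2 without node knockout replicate 1 or 2. The adjusted p of Cnih2 ranged from 0.00592 to 0.132 with a library left out, that of Hist1h1b from 0.0122 to 0.173, that of Prdx4 from 0.00467 to 0.144 and that of Uhrf1 from 0.00403 to 0.3302.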

How the results depend on the processing

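Tests chosen after seeing the data were those without cycling cells, without genes within 20 Mb of Cd69, without genes overlapping another gene, within single clusters of a class, and lymph node cells clustered again without called genes; the other alternatives were planned. Over the alternatives, 307 of the values that answer a comparison kept their direction and their side of the threshold, or, for counts, stayed within 1.5 times and, for shares and r, within 1 SD, while 140 moved and 2 weakened. Among the named genes, those that passed the test kept direction and side in 743 checks and kept direction without passing in 129, and none of them turned. Of the named genes that did not pass, 1777 checks were alike, 19 passed and 100 changed sign. Unless stated, the cause was not tested. With 2 libraries per group, few degrees of freedom stand behind each test, and a library left alone in its group was assumed to vary like the other groups.

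The DESeq2 Wald test gave 801 for the knockout in tumours, 331 for the knockout in nodes, 248 for the difference of the knockout effects, 8 for anti-CD69 against IgG, 6 for anti-PD-1 against IgG, 177 for the combination against IgG, 2 for the combination against anti-PD-1, 57 for the combination against anti-CD69, 9 for the antibody interaction and 126 for the knockout effect minus the anti-CD69 effect. Testing every gene with at least 1 count gave 187 for the knockout in nodes, 67 for the difference of the knockout effects, 1 for anti-CD69 against IgG, 3 for anti-PD-1 against IgG, 9 for the combination against IgG, 2 for the combination against anti-CD69, 1 for the antibody interaction and 50 for the knockout effect minus the anti-CD69 effect. A fit to the libraries of each comparison alone gave 6 for the knockout in tumours, 2334 for the knockout in nodes, 1 for the difference of the knockout effects, 264 for the combination against IgG, 6 for the combination against anti-PD-1, 13 for the combination against anti-CD69 and 6 for the knockout effect minus the anti-CD69 effect. That fit holds fewer libraries and takes the spread from them alone, and in tumours the replicates spread more than in nodes. RLE size factors and the stricter cell filter moved none of these counts by over 1.5 times. With all barcodes that passed the cell filter the difference of the knockout effects gave 7 genes, and thinned counts gave 2 genes for the combination against anti-CD69. Summing cells outside the cycling clusters gave 42 genes for the knockout in nodes and 4 for the difference of the knockout effects. Without genes within 20 Mb of Cd69, 10 genes differed between the knockout and anti-CD69 effects, since genes of the region were among the 21.

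A replicate number as a block was only an alternative, as pairing is not stated. Across genes, residuals of the same number correlated between groups with r from -0.159 for IgG and anti-CD69 to 0.456 for wild type and knockout in tumours, and r was -0.0277 in nodes. The block gave 887 for the knockout in tumours, 285 for the knockout in nodes, 146 for the difference of the knockout effects, 67 for the combination against IgG, 1 for the combination against anti-PD-1, 15 for the combination against anti-CD69, 4 for the antibody interaction and 88 for the knockout effect minus the anti-CD69 effect. In progenitor-like cells it gave 343 for the knockout in tumours, 30 for the knockout in nodes, 23 for anti-CD69 against IgG, 50 for anti-PD-1 against IgG and 74 for the combination against IgG. In terminally exhausted-like node cells it gave 68 for knockout against wild type. In tumour cluster 0 it gave 168 for knockout against wild type, 38 for anti-CD69 against IgG, 27 for anti-PD-1 against IgG and 57 for the combination against IgG. The block called 11 clusters in tumours, over all comparisons, and 1 in nodes.

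With an estimated correlation 1 list call passed, against 101 with 0.01. Across genes, r between the knockout and anti-CD69 effects was 0.163 over genes with a mean CPM of at least 20, and r between the anti-CD69 effect and the combination against anti-PD-1 was -0.322. At a clustering resolution of 0.4 the lower share of naive-like cells in knockout nodes had a log2 ratio of -0.53 and did not pass. Within single clusters of a class, cluster 2 gave 0 genes for each antibody comparison (without combination replicate 1, 46 for the combination against IgG and 4 against anti-PD-1; otherwise at most 3). Cluster 3 gave 4 for anti-PD-1 against IgG (0 without IgG replicate 1 or either anti-PD-1 library, 5 without IgG replicate 2) and 2 for the combination against IgG (0 without IgG replicate 1 or combination replicate 2, 1 without IgG replicate 2, 72 without combination replicate 1), and 0 for the combination against anti-PD-1 (11 without combination replicate 1). For knockout against wild type, tumour cluster 2 gave 78 (7 to 164 with a library left out), tumour cluster 3 gave 124 (24 to 63), node cluster 7 gave 7 (5 to 6) and node cluster 14 gave 23 (4 to 8). Without thinning, the difference in percentage points of Havcr2-only cells was 11.2 for the knockout in tumours, 4.32 in nodes and 5.96 for anti-CD69 against IgG, and at 2000 UMIs it was 1.63 in nodes and 2.54 for anti-CD69. The difference of Tcf7-only cells was -19.5 in nodes, -4.16 for anti-CD69 and -0.848 for the combination against IgG without thinning, and -11.0 in nodes and 0.340 for the combination at 2000 UMIs.

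Leaving out each library in turn, the number of genes ranged from 26 to 657 for the knockout in tumours, 1 to 356 for the difference of the knockout effects, 7 to 218 for the knockout effect minus the anti-CD69 effect, 3470 to 5588 for tumour against node in knockout, 0 to 2 for anti-CD69 against IgG, 0 to 49 for the combination against IgG, 0 to 17 for the combination against anti-CD69 and 16 to 34 for the knockout in nodes. In progenitor-like cells it was 30 to 200 for the knockout in tumours, 0 to 2 for anti-CD69 against IgG, 0 each time for anti-PD-1 against IgG, 0 to 51 for the combination against IgG and 8 to 11 for the knockout in nodes. In tumour cluster 0 it was 11 to 56 for knockout against wild type, 0 to 2 for anti-CD69 against IgG, 0 to 52 for the combination against IgG and 0 to 10 for the combination against anti-PD-1. In terminally exhausted-like node cells it was 10 to 18 for knockout against wild type. The number of clusters called ranged from 0 to 6 in tumours and from 0 to 10 in nodes, and the log2 ratio of circulating effector-like cells in nodes from 1.36 to 2.03 in the first clustering, against 1.65 with all libraries and 0.80 clustered without called genes, where the class held other cells in part. In the first it did not pass without node knockout replicate 2 (log2 1.47, adjusted p = 0.0556). Across genes, r ranged from -0.117 to 0.110 for the knockout and anti-CD69 effects, from 0.182 to 0.275 for the knockout effects in the tissues, and from -0.208 to 0.0323 for anti-CD69 against IgG and the combination against anti-PD-1. The direction of these lists turned for 1 library left out: G2/M genes in knockout tumours without knockout replicate 2 (adjusted p from 6.45e-12 to 0.364), G2/M genes in the knockout effect minus the anti-CD69 effect without knockout replicate 2 (from 1.93e-09 to 0.628), cytotoxic genes in wild type against IgG without wild-type replicate 1 (from 2.23e-05 to 0.658), and hypoxia genes under anti-CD69 without anti-CD69 replicate 2 (from 1.93e-06 to 0.269).

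The named genes whose log2 fold change crossed 0 passed the test in none of these settings. With RLE size factors or DESeq2, the value was 0.015 for Itgae in the knockout in tumours and -0.015 for Cd69 in the antibody interaction. With no filter on low counts, the value was 0.0086 for Itgae in the knockout in tumours and -0.027 for Cd69 in the antibody interaction. With the block, the value was -0.035 for Ifng in the knockout in tumours. With the stricter cell filter, the value was -0.0052 for Klf2 in the combination against IgG and -0.018 for Cd69 in the antibody interaction. With no cycling cells, the value was -0.045 for Ifng in the knockout in tumours, -0.052 for Mki67 in the knockout in nodes, 0.035 for Itgae in anti-PD-1 against IgG, -0.13 for Cx3cr1 in anti-PD-1 against IgG, -0.18 for Il7r in the combination against IgG, 0.050 for Nr4a1 in the combination against IgG, 0.033 for Havcr2 in the combination against anti-PD-1, 0.0039 for Gzmb in the combination against anti-PD-1, 0.027 for Cd69 in tumour against node in wild type and -0.023 for Cd69 in wild type against IgG. With thinned counts, it was -0.082 for Itgae in anti-CD69 against IgG. With the libraries of the comparison alone, it was -0.011 for Cd69 in the antibody interaction.

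Leaving out each library in turn also took genes that did not pass across 0. In the knockout in tumours the log2 fold change ranged for Pdcd1 -0.069 to 0.26, Tcf7 -1.16 to 0.14, Slamf6 -0.080 to 0.54, Prf1 -0.36 to 0.62, Ifng -0.64 to 0.49, Ccl4 -0.62 to 0.93, Itgae -0.65 to 0.37 and Nr4a1 -0.58 to 0.20. In anti-CD69 against IgG it ranged for Pdcd1 -0.39 to 0.020, Slamf6 -0.38 to 0.27, Il7r -0.37 to 0.26, S1pr1 -0.43 to 1.09, Klf2 -0.31 to 0.85, Tox -0.27 to 0.058, Lag3 -0.14 to 0.19, Entpd1 -0.017 to 0.40, Gzmb -0.14 to 0.42, Prf1 -0.078 to 0.71, Itgae -0.11 to 0.26, Cxcr6 -0.0059 to 0.51 and Mki67 -0.66 to 0.090. In anti-PD-1 against IgG it ranged for Tcf7 -0.47 to 0.89, Slamf6 -0.046 to 0.76, Klf2 -0.28 to 0.29, Entpd1 -0.16 to 0.27, Gzmb -0.0094 to 0.56, Prf1 -0.30 to 0.60, Ifng -0.11 to 0.30, Itgae -0.32 to 0.025, Cxcr6 -0.31 to 0.46 and Cx3cr1 -0.073 to 0.11. In the combination against IgG it ranged for Il7r -0.25 to 0.38, Klf2 -0.28 to 0.24, Havcr2 -0.10 to 0.87, Entpd1 -0.19 to 0.28, Cxcr6 -0.11 to 0.078 and Nr4a1 -0.12 to 0.073. In the combination against anti-PD-1 it ranged for Tcf7 -0.66 to 0.71, Slamf6 -0.27 to 0.54, S1pr1 -0.62 to 1.03, Klf2 -0.32 to 0.28, Havcr2 -0.63 to 0.34, Entpd1 -0.22 to 0.22, Gzmb -0.30 to 0.27, Prf1 -0.75 to 0.15, Cxcr6 -0.50 to 0.27 and Mki67 -0.19 to 0.41. In the combination against anti-CD69 it ranged for Pdcd1 -0.39 to 0.019. In the antibody interaction it ranged for Cd69 -0.080 to 0.10 and Pdcd1 -0.28 to 0.14. In tumour against node in wild type it ranged for Cd69 -0.31 to 0.00061. In wild type against IgG it ranged for Cd69 -0.12 to 0.20 and Pdcd1 -0.15 to 0.10.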

Other observations

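The tests of flanking DNA, of the blocking antibody, of monocytes and of a single library were chosen after the result was seen, and the tests of paralogs, of tumour cluster 8 and of the gene annotation were planned before it.

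Tumour cells differed from node cells in further lists in the wild type. Heat shock and dissociation stress genes rose in 15 of 17 (adjusted p = 1.0e-05; adjusted p = 0.0940 with an estimated correlation) and hypoxia genes in 11 of 15 (adjusted p = 0.00323; adjusted p = 0.368 with an estimated correlation), with equal counts adjusted over the list alone. Early T cell receptor genes rose in 14 of 22, with 2 fallen, and 15 rose adjusted over the list alone (adjusted p = 0.000655; adjusted p = 0.167 with an estimated correlation). Naive and memory genes fell in 11 of 15, also adjusted over the list alone (adjusted p = 0.000733; adjusted p = 0.339 with an estimated correlation), with -4.28 for Lef1. In the knockout, 7 of 9 macrophage and monocyte genes were higher in tumours, also adjusted over the list alone (adjusted p = 0.000581; adjusted p = 0.0882 with an estimated correlation).

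Large changes lay near Cd69 on chromosome 6. If blocking CD69 caused them, anti-CD69 would move the same genes, but their median anti-CD69 log2 value, signed by the knockout, was 0.080 (95% bounds -0.031 and 0.142), against a median absolute knockout value of 2.15, which argues against it. The odds ratio of a call within 20 Mb was 7.27 in nodes (95% interval 3.88 to 12.8, Fisher's exact test) and 2.72 in tumours. This restates the pattern and favours no cause. DNA around the Cd69 allele that differs from the wild type cannot be told from other causes. For Cdca3 these include cycling. Reads shared between paralogs stay open too. Without genes named Klr or Clec the odds ratio in nodes was 3.1 (95% interval 1.102 to 7.07), too wide to decide. In tumours it was 1.27 (95% interval 0.502 to 2.69). An effect of CD69 loss that antibody does not cause stays open and untested. The history of the knockout strain is not given, and Sfmbt2, on chromosome 2, lies outside the region.

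Ly6c1, Ly6c2, Ly6a and Ccl5 were higher in knockout tumours. Monocytes among the sorted cells would bring Lyz2, but the mean CPM of Lyz2 gained 0.501% of what that of Ly6c2 gained, and the sort for CD8 and tetramer should remove them. Knockout replicate 2 alone, and a larger share of the cells of cluster 8, were argued against by medians of 1.91 without that library and 2.15 outside that cluster, against 2.33 in all cells. Without that library the log2 values were 2.00 ± 0.39 for Ly6c1, 1.82 ± 0.34 for Ly6c2, 2.05 ± 0.42 for Ly6a and 1.04 ± 0.33 for Ccl5, against 2.39 ± 0.37, 2.36 ± 0.36, 2.29 ± 0.38 and 1.48 ± 0.32, and the calls ended (adjusted p = 0.0583, 0.0581, 0.0629 and 0.179), as the values were smaller and 1 knockout library was left, and outside cluster 8 Ccl5 did not pass (1.15, adjusted p = 0.0568). Loss of Cd69 may raise these genes in tumours, a hypothesis found on the same data, and in nodes the values were 0.17 for Ly6c1, 0.23 for Ly6c2 and 0.08 for Ly6a, none of which passed, and 1.53 for Ccl5.

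Of the genes tested, 7 were below 1 CPM in every tumour library and at 20 CPM or more in nodes: Cpne1, Tmsb15b2, Dtx1, Igflr1, Fdx2, 4930486L24Rik and Fam89b. An exon of another gene on the same strand overlapped 85.7% of them (95% interval 42.1 to 99.6%), against 9.68% of other genes at that level, so overlapping gene models counted differently by the annotation of each tissue are a candidate explanation. For the 14.3% without an overlap (95% interval 0.361 to 57.9%), which is Dtx1, a difference between tumour and node cells cannot be told apart from other causes, as it is a single gene. Tissue and annotation coincide in every library.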
